A study of Mus musculus with 15 samples.

How the data were processed

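T-cell receptor beta chain (TCRβ) repertoires were measured in CD8 T cells of non-obese diabetic (NOD) mice, a strain that develops autoimmune diabetes, at 125 days of age. Wild-type (WT) mice and mice with a mutation of Ifngr1, which encodes a chain of the interferon-γ receptor, were compared. Spleen and non-draining lymph node cells were pooled per mouse, stained with a tetramer of H-2Kd loaded with the IGRP206–214 peptide, an autoantigen of pancreatic beta cells, and separated on a magnetic column. The cells that bound the tetramer gave the TET libraries, and the CD8+CD44+ cells that passed through gave the CD8 libraries. The groups were WT TET (n = 3), mutant TET (n = 4), WT CD8 (n = 4) and mutant CD8 (n = 4), 15 libraries in all. The TET library of the 4th WT mouse was not analysed here.

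According to the submitters' protocol, total RNA was reverse transcribed with a TCRβ constant region primer, 9-nt unique molecular identifiers (UMIs) were added by template switching, and the products of nested PCR were sequenced on a MiSeq instrument. The authors deposited 1 table per library, with a count for each distinct nucleotide CDR3. The tables do not say whether the counts are reads or UMIs, so intervals and limits given for shares cover counting error only. The deposited fraction of each clonotype is its count divided by a library total that includes sequences left out of the table, and the tables held between 94.2% and 99.2% of that total. The deposited tables also give the CDR3 length in amino acids. The aligner, clonotype caller and genome build are not given in the sources used here. All shares were recomputed from the counts in the tables.

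A clonotype was a distinct combination of V family, J segment and nucleotide CDR3. The tables name V segments only as families, so TRBV13-1, TRBV13-2 and TRBV13-3 could not be separated. They name the J cluster but not the J segment. J segments were therefore assigned from the last 12 nucleotides of the CDR3 with at most 2 mismatches, against J segment ends entered by hand, and 342 clonotypes (0.576%) stayed unassigned. As a check, the J length given in the tables was 19 nucleotides above the RefSeq length of the assigned segment (assembly GRCm38.p6) in all but 16 of the assigned clonotypes. Before any test, 4 entries of alpha chain segments, with 6 counts, were left out, and 59364 clonotypes remained, 5545 of them in TET libraries. No out-of-frame sequence and no stop codon was found in the tables. Total counts ranged from 2536 to 60164 in the TET libraries and from 17116 to 32856 in the CD8 libraries. A clonotype not seen in a library could make up as much as 0.00499% of the deepest library and 0.118% of the shallowest (3 counts).

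Comparisons, tests and alternatives were fixed before the data were examined, with the exceptions named here and in the later sections. The number of clonotypes was given at full depth and after rarefaction to the smallest library of the comparison, 2536 counts for TET and for comparisons of the fractions, and 17116 counts for CD8. The effective number of clonotypes, exp(Shannon entropy), was the mean of 200 seeded subsamples. Single values were compared with two-sided exact permutation tests on differences of group means, over 35 splits for 3 against 4 libraries (smallest p 0.0286) and 70 for 4 against 4 (smallest p 0.0286). TET was compared with CD8 by reassigning the fraction within each strain, over 2450 assignments (smallest p 0.000408). Benjamini-Hochberg adjusted values cover the 17 exact tests together.

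Clonotypes per V family (23 found) and J segment (12 found) were compared with edgeR's quasi-likelihood test, with the number of assigned clonotypes as library size, no further normalization, and the filterByExpr minimum count of 10. Each clonotype counted once. A segment was called at an adjusted p under 0.05, over the V families or over the J segments of a comparison. TET against CD8 was fitted with strain as a covariate. The difference of the strain effects in TET and in CD8 was tested as a contrast of the 4 groups. With so few segments, no trend of the dispersion on abundance was fitted. DESeq2 was run with the filterByExpr minimum count of 10 as well, and with a mean dispersion fit. These dispersion settings were chosen after the data were seen, as were the library size and the assignment of J segments.

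Same-numbered TET and CD8 libraries of a strain were taken as 1 mouse, since the design text counts 4 mice per strain for both fractions; this gives 7 mice with both. As a check, the deviations of V family use from the group mean, over 15 families, correlated between same-numbered libraries with r of -0.540, 0.148 and 0.572 in WT and -0.0405, -0.0744, 0.0971 and -0.189 in mutant mice, and the own CD8 library gave the highest r in 1 of 7. The values are across families, which are not independent replicates. The pairing therefore rests on the design text and not on these values. Between strains, the numbers were not taken to pair the mice. None of the 105 pairs of libraries was identical, and at most 15.9% of the clonotypes of the smaller library were shared. That highest value was for WT TET 2 with mutant CD8 4, with 20 shared clonotypes, against 6 for WT TET 2 with WT CD8 2.

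The segments and clonotypes named were chosen by a rule fixed before the data were examined. It takes every called segment, up to 10 higher and 10 lower by size of change, and all members of fixed lists. The lists are the TRBV13 family, whose products include Vβ8.1, the beta chain of the IGRP-specific clone NY8.3; segments of invariant NKT cells (TRBV13, TRBV29, TRBV1) and MAIT cells (TRBV19, TRBV13), which a CD8 gate could hold; TRBV26; V pseudogenes; TRBJ2-4; and the TRBJ1 and TRBJ2 clusters. For clonotypes, by V, J and amino acid CDR3, it takes the largest of each TET library and at most 10 of those found in at least 3 TET libraries. Intervals of shares are exact Clopper-Pearson intervals at the 95% level.

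The tests were checked on simulated data. Over 2000 simulated sets, the stratified exact test gave p under 0.05 in 4.70% of unchanged and 100% of shifted sets, and the sign-flip test in 5.20% of unchanged sets. The shift was several times the SD of the simulated values, so the 100% does not measure power. The power of the exact test between strains was not simulated. Over 100 simulations per comparison with 1 segment doubled or halved, edgeR called the doubled V family in 67% and the halved one in 50% for TET mutant against WT (8 families), 99% and 98% for CD8 mutant against WT (17 families), and 100% and 100% for TET against CD8 (15 families). For the 12 J segments, the calls were 70% and 57%, 100% and 100%, and 100% and 100% in the same order. Unchanged segments were called in 0.0667% to 0.500% of cases. The counts were simulated from a negative binomial model, and the common dispersion was 9.77e-05 for V families in TET between strains, close to counting error alone. These rates hold for that model and may not hold for libraries that vary more between mice.

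Alternatives were clonotypes with a count of 1 left out, clonotypes defined by amino acid CDR3, near-identical clonotypes merged at a count ratio of 10, rarefaction to 1268 counts (TET) and 8558 counts (CD8), clonotypes weighted by their counts, TMM factors, DESeq2, no filter on rare segments, all 15 libraries in 1 fit, each strain alone, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were clonotypes of at least 0.1% of the counts, the 90 largest clonotypes of each library, V and CDR3 values in rarefied libraries, removal of clonotypes that another library held at 10 times the count or more, and leaving out WT TET 2 and mutant TET 4 together. The alternatives for the difference of the strain effects were added then as well. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.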

Results

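TCRβ repertoires of IGRP-tetramer-binding CD8 T cells (TET) and of CD8+CD44+ T cells that did not bind the tetramer (CD8) were compared between WT and Ifngr1-mutant NOD mice. The WT TET libraries held 4968, 14958 and 2536 counts, and the mutant TET libraries 17294, 22448, 21966 and 60164. The CD8 libraries held 17116 to 27836 counts in WT mice (n = 4) and 20909 to 32856 in mutant mice (n = 4). Values are means ± SD over libraries.

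Whether loss of interferon-γ receptor signalling changes the breadth of the IGRP-specific repertoire was addressed by counting clonotypes. TET libraries held 108 ± 15.5 clonotypes in WT mice (n = 3) and 1305 ± 781 in mutant mice (n = 4), and each mutant library held more than each WT library. The ratio of geometric means was 10.1 (two-sided exact permutation p = 0.0571, adjusted 0.162). At equal depth the TET libraries held 91.5 ± 8.28 clonotypes in WT and 563 ± 355 in mutant mice, a ratio of 4.52 (exact p = 0.143, adjusted 0.304). The effective number of TET clonotypes, which weighs each clonotype by its share, was 42.8 ± 19.2 in WT and 172 ± 108 in mutant mice, a ratio of 3.07 (exact p = 0.171, adjusted 0.324). The 10 largest TET clonotypes took 48.9 ± 21.9% of the counts in WT and 45.5 ± 18.2% in mutant mice (exact p = 0.714). None of these differences passed the test. Mutant TET 4, the deepest library, stood apart with few clonotypes: without it the ratios were 14.2, 7.77 and 5.49, each with exact p = 0.1, the smallest that 3 against 3 libraries allow, and without WT TET 2 as well they were 15.4, 7.37 and 4.20; among clonotypes of at least 0.1% of the counts the ratio of numbers was 1.47 (exact p = 0.429). Without WT TET 2 or mutant TET 1 the difference in the share of the 10 largest turned to 8.80 and 0.753 percentage points. Equal depth in counts does not equalize the number of cells per library, which was not taken into account. The median count of a clonotype was 19.5 ± 8.26 in WT and 3.5 ± 1.91 in mutant TET libraries. Fewer cells in the WT libraries and a narrower WT repertoire therefore cannot be told apart by these ratios.

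In the CD8 fraction, the background measured in the same mice, clonotypes numbered 5736 ± 2804 in WT and 7719 ± 2564 in mutant mice (n = 4 each), a ratio of 1.46 (exact p = 0.429, adjusted 0.518). At equal depth the CD8 libraries held 5091 ± 2314 and 6469 ± 1777 clonotypes, a ratio of 1.37 (exact p = 0.457). The effective numbers were 3793 ± 1887 and 4770 ± 1370, a ratio of 1.38 (exact p = 0.457). Without WT CD8 1, which held 2040 clonotypes, these ratios were 1.08, 1.04 and 1.03. The 10 largest CD8 clonotypes took 2.47 ± 1.34% of the counts in WT and 2.66 ± 1.3% in mutant mice (exact p = 0.714), a difference that turned to -0.213 without WT CD8 4 and -0.436 without mutant CD8 4. The strain difference in the effective number was larger in TET than in CD8 by 1.28 on the log2 scale, which did not pass the test (exact p = 0.286 over the 7 mice with both fractions); this value was 2.13 without mutant TET 4 and 0.79 without WT TET 2.

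TET repertoires were dominated by few clonotypes beside CD8 repertoires in both strains. Rarefied to 2536 counts, CD8 libraries had effective numbers of 1577 ± 445 (WT) and 1773 ± 181 (mutant), and TET libraries a 23.6-fold lower one, averaged over strains (exact p = 0.000408, the smallest that these permutations give, adjusted 0.00231). This is a ratio of 0.0424, which was 0.0649 at a depth of 1268 counts and 0.0649 without both WT TET 2 and mutant TET 4. The share of the 10 largest clonotypes was 44.6 percentage points higher in TET (exact p = 0.000408, adjusted 0.00231). The number of cells per library was not taken into account between fractions either.

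**Figure D1:**
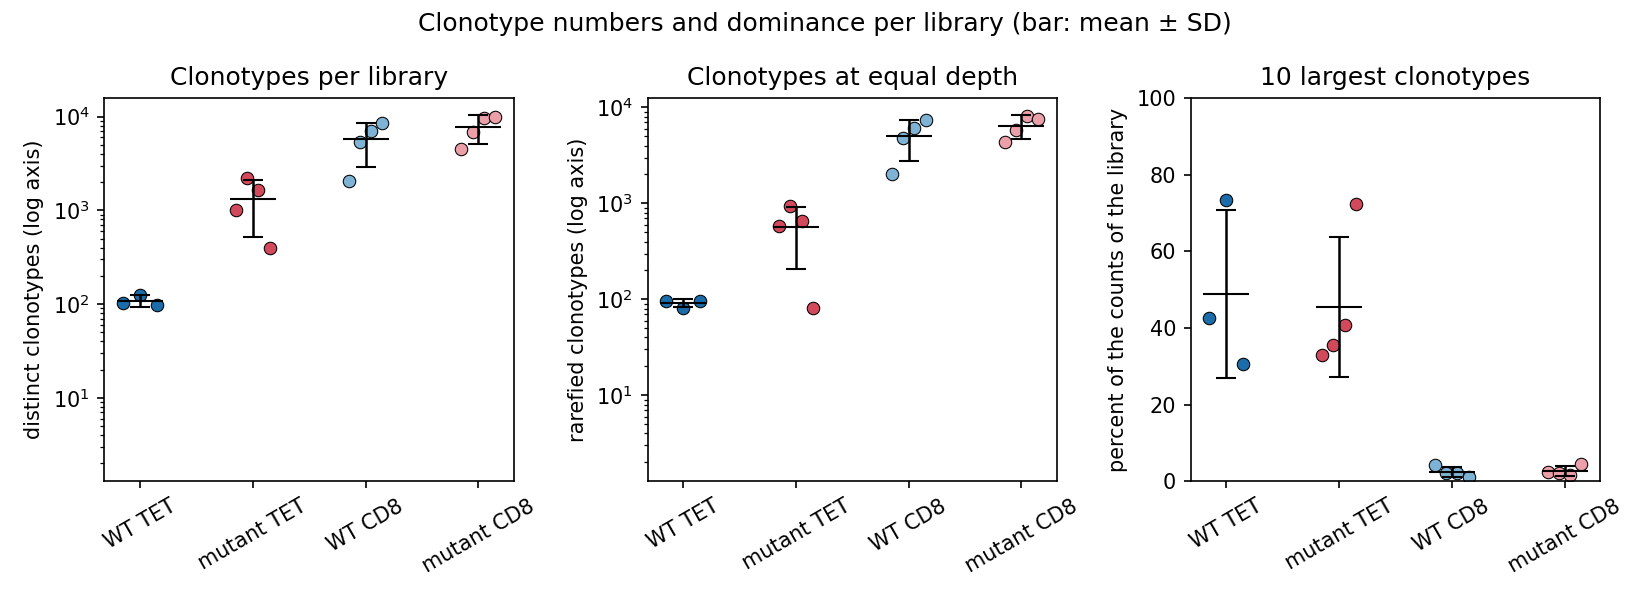
Distinct clonotypes per library (left, log axis), clonotypes after rarefaction to the smallest library of each fraction (middle, log axis) and the percent of counts in the 10 largest clonotypes (right); points are libraries, bars mean ± SD. WT TET libraries lie between 97 and 126 clonotypes and mutant TET libraries between 393 and 2199.

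TRBV13, the family used by the IGRP-specific clone NY8.3, made up 51.2 ± 7.79% of TET clonotypes (n = 7) and 35.2 ± 1.32% of CD8 clonotypes (n = 8). By counts its share was 83.3 ± 10.1% in TET and 49.0 ± 3.57% in CD8. TRBV31 and TRBV20, each under 2% of CD8 clonotypes, rose to 3.83 ± 1.84% and 4.70 ± 1.94% of TET clonotypes. Their TET shares were 5.12 ± 0.992% and 5.59 ± 1.37% in mutant mice, and 2.12 ± 0.982% and 3.52 ± 2.18% in WT. TRBV12 nearly disappeared, with 4 of 5545 TET clonotypes (0.0715 ± 0.109% per library) against 6.37 ± 0.327% in CD8. TRBV16 fell from 7.91 ± 0.696% to 0.579 ± 0.561%, TRBV15 from 3.50 ± 0.294% to 0.584 ± 0.654%, and TRBV3 from 4.63 ± 0.524% to 1.55 ± 0.861%.

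The TRBV13 share of clonotypes was 16.9 percentage points higher in TET, averaged over strains (exact p = 0.000408, the smallest possible, adjusted 0.00231). With edgeR, 13 of 15 tested V families differed, 6 higher in TET and 7 lower. The log2 fold changes (SE) of the higher families were 1.79 (0.15) for TRBV31, 1.78 (0.15) for TRBV20, 0.87 (0.11) for TRBV1, 0.71 (0.16) for TRBV2, 0.61 (0.12) for TRBV5 and 0.48 (0.06) for TRBV13, with adjusted p up to 0.000156. Those of the lower families were -6.41 (0.29) for TRBV12, -4.10 (0.20) for TRBV16, -3.29 (0.24) for TRBV15, -2.08 (0.19) for TRBV3, -1.45 (0.15) for TRBV17, -1.12 (0.15) for TRBV14 and -0.88 (0.13) for TRBV29, with adjusted p up to 1.9e-07. TRBV19 (0.08) and TRBV4 (0.00) did not pass. Weighted by counts, 10 families were called, 1 higher and 9 lower. TRBV1, TRBV2, TRBV5 and TRBV31 then had log2 fold changes of -0.52, -0.44, -0.66 and -0.14, and TRBV20 had 0.51, none called. In WT mice alone, with 3 TET libraries, 6 families were called, 1 higher and 5 lower, and TRBV5 had a log2 fold change of -0.12. There TRBV31 (0.45, edgeR adjusted p = 0.524), TRBV20 (0.92, 0.261), TRBV1 (0.69) and TRBV2 (0.22) were not called, nor were TRBV3 (-1.12) and TRBV29 (-0.54).

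Among the lists fixed in advance, the invariant NKT segments TRBV13 and TRBV1 were higher in TET and TRBV29 lower (3 of 3 called, also when adjusted over the list alone), so the members moved in both directions. Of the MAIT segments TRBV13 was higher and TRBV19 not called (1 of 2 called, also when adjusted over the list alone). TRBV26, a family deleted by endogenous superantigens in several mouse strains, was too rare to test in TET, with 4 clonotypes (0.242 ± 0.594%) against 0.389 ± 0.0707% in CD8. Of the V pseudogenes, TRBV10 had 7 TET and 21 CD8 clonotypes, TRBV8 had 1 and 3, TRBV21 had 0 and 5, and TRBV9 had 0 and 1.

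J use differed between the fractions by cluster. All 6 TRBJ1 segments were higher among TET clonotypes and 5 of 6 TRBJ2 segments lower (edgeR, 11 of 12 called; 6 and 5 also when adjusted over the list alone). TRBJ1-2 made up 6.12 ± 1.2% of TET and 3.74 ± 0.284% of CD8 clonotypes, and TRBJ1-5 made up 4.31 ± 1.52% and 2.21 ± 0.289%. The log2 fold changes (SE) were 0.80 (0.11) for TRBJ1-2, 0.78 (0.14) for TRBJ1-5, 0.71 (0.09) for TRBJ1-4, 0.58 (0.11) for TRBJ1-3, 0.55 (0.08) for TRBJ1-1 and 0.42 (0.12) for TRBJ1-6. They were -0.53 (0.08) for TRBJ2-1, -0.44 (0.07) for TRBJ2-7, -0.29 (0.11) for TRBJ2-2, -0.27 (0.09) for TRBJ2-5 and -0.22 (0.09) for TRBJ2-4, and TRBJ2-3 (-0.05) was not called; adjusted p of the called segments went up to 0.0203. TRBJ2-4, the J segment of NY8.3, was lower by clonotypes, but took 21.8 ± 17.5% of TET counts and 9.91 ± 0.490% of CD8 counts. Its call was lost with the mouse as a block (adjusted p = 0.278) and without mutant TET 2 (log2 fold change -0.08) or mutant TET 3 (-0.17), as was that of TRBJ2-2 without mutant TET 2 (-0.24) and without single-count clonotypes (-0.19, adjusted p = 0.133). The TRBJ2-4 call was also lost with DESeq2 (adjusted p = 0.101) and without single-count clonotypes (adjusted p = 0.121 in edgeR), and that of TRBJ1-6 with TMM factors (adjusted p = 0.0783). No J segment was called by counts (2 with unadjusted p under 0.05), where 8 of the called segments had the opposite sign. In WT mice alone TRBJ1-5 was the 1 segment called, and the pattern by cluster did not hold: TRBJ1-3 (log2 fold change -0.32), TRBJ1-6 (-0.82) and TRBJ2-4 (0.53) went the other way, as did TRBJ1-4 (-0.0074) and TRBJ2-2 (0.056).

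**Figure D2:**
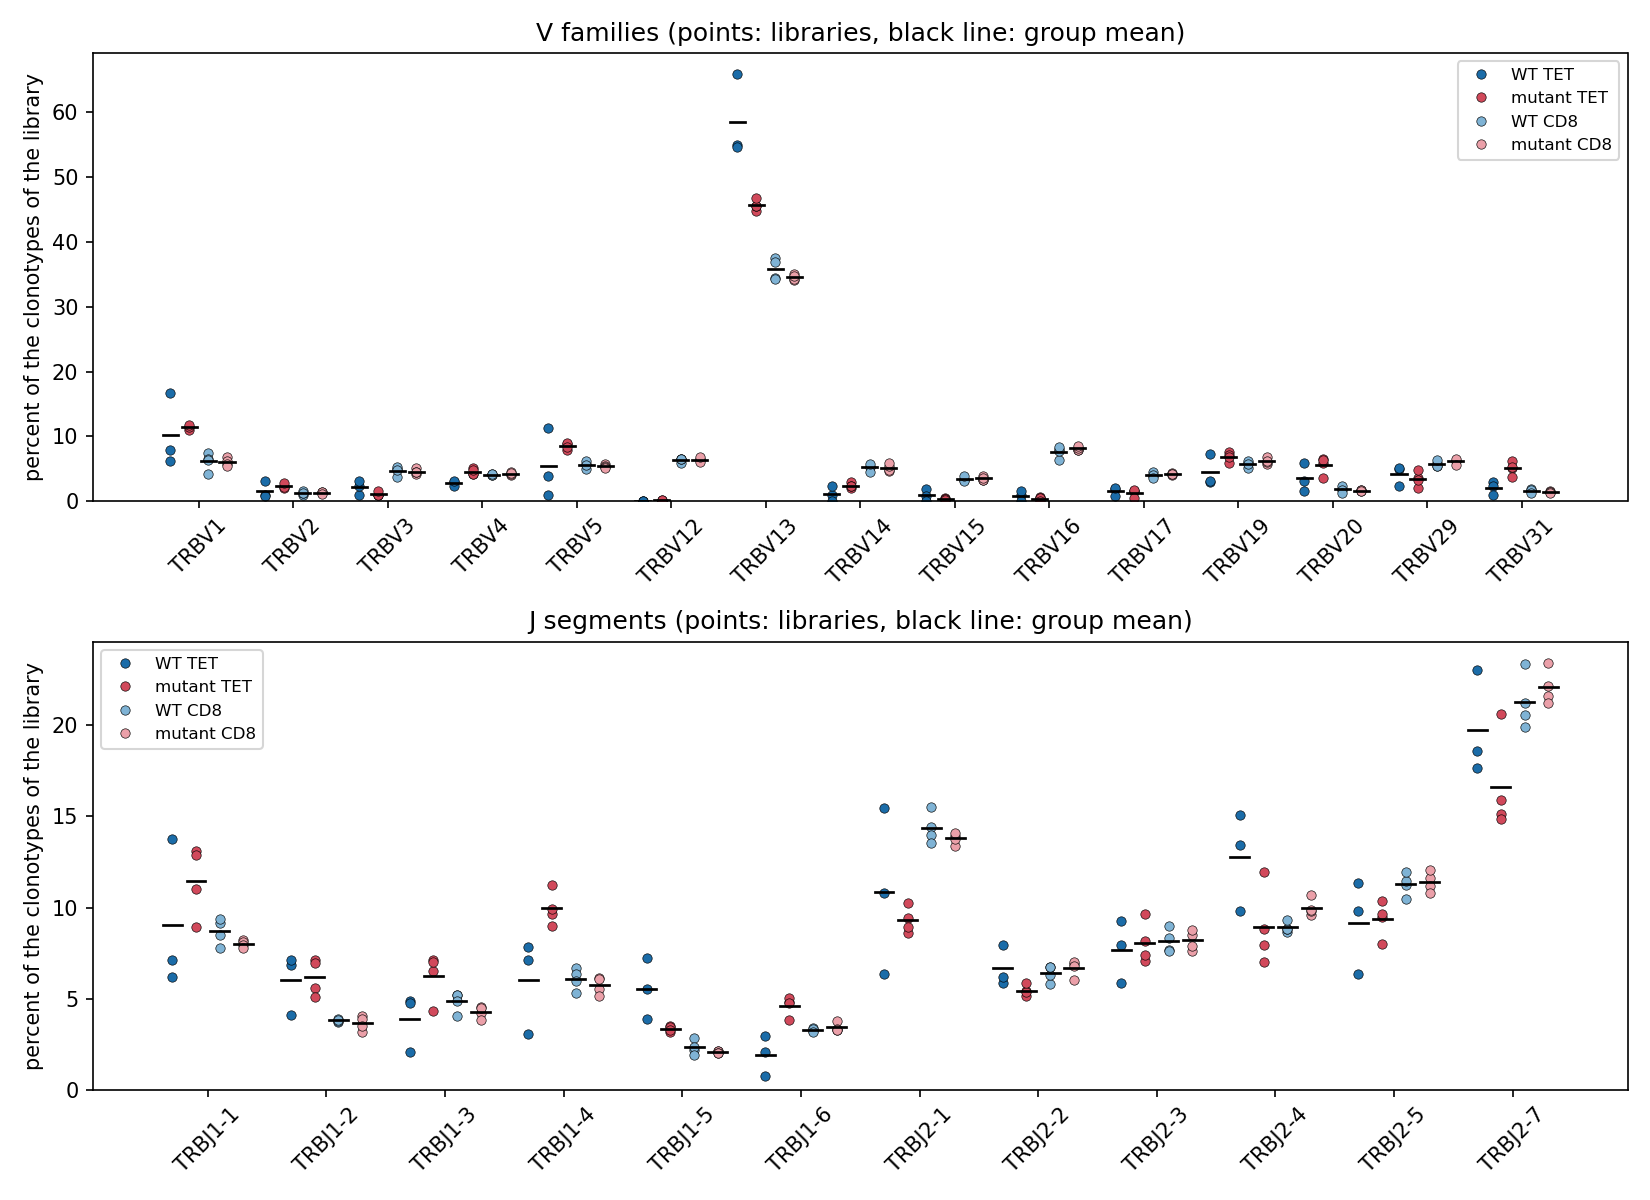
Percent of the clonotypes of each library in the V families tested between fractions (top) and in the J segments (bottom); points are libraries, black lines group means. TRBV13 lies between 54.6 and 65.9% in WT TET libraries, 44.8 and 46.8% in mutant TET and 34.1 and 37.6% in CD8, and TRBV12 is nearly absent from TET.

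Between the strains, TRBV13 took a smaller part of the mutant TET clonotypes, 45.7 ± 0.825% (n = 4) against 58.5 ± 6.41% in WT (n = 3), and each mutant library lay below each WT library. Its share of the TET counts was 83.3 ± 8.3% in mutant and 83.4 ± 14.1% in WT mice. The difference in clonotypes was -12.8 percentage points (exact p = 0.0286, the smallest possible, adjusted 0.0971), so it did not pass the correction. With edgeR, TRBV13 fell by 0.38 on the log2 scale (SE 0.12, adjusted p = 0.0358), the 1 family called of 8 tested. TRBV31 (log2 fold change 1.29, adjusted p = 0.0780), TRBV20 (0.82), TRBV1 (0.15), TRBV19 (0.65) and TRBV29 (-0.29) did not pass. The lists of NKT and MAIT segments each had TRBV13 as their 1 called member, also when adjusted over the list alone. The difference depended on which clonotypes were counted: at equal depth it was -2.79 percentage points (exact p = 0.714), and among the 90 largest clonotypes of each library TRBV13 made up 60.0 ± 12.5% in WT and 93.6 ± 7.82% in mutant mice, 33.6 points in the other direction (exact p = 0.0286). The 90 largest were 71.4 to 92.8% of the clonotypes of WT and 4.09 to 22.9% of those of mutant libraries, so this sets unlike parts of the size range against each other. Among clonotypes of at least 0.1% of the counts the difference was 27.4 points (exact p = 0.0857). That limit also kept a larger part of WT libraries (58 to 84 of 97 to 126 clonotypes) than of mutant ones (34 to 217 of 393 to 2199). The edgeR call was lost with a smaller fold with TMM factors (log2 fold change -0.12, adjusted p = 0.438), without single-count clonotypes (-0.23, 0.560), without WT TET 2 (-0.27, 0.264) and without both WT TET 2 and mutant TET 4 (-0.27, 0.269). It was lost at the main fold, with fewer libraries, without mutant TET 2 (-0.38, 0.0667) or mutant TET 3 (-0.38, 0.0737).

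**Figure D3:**
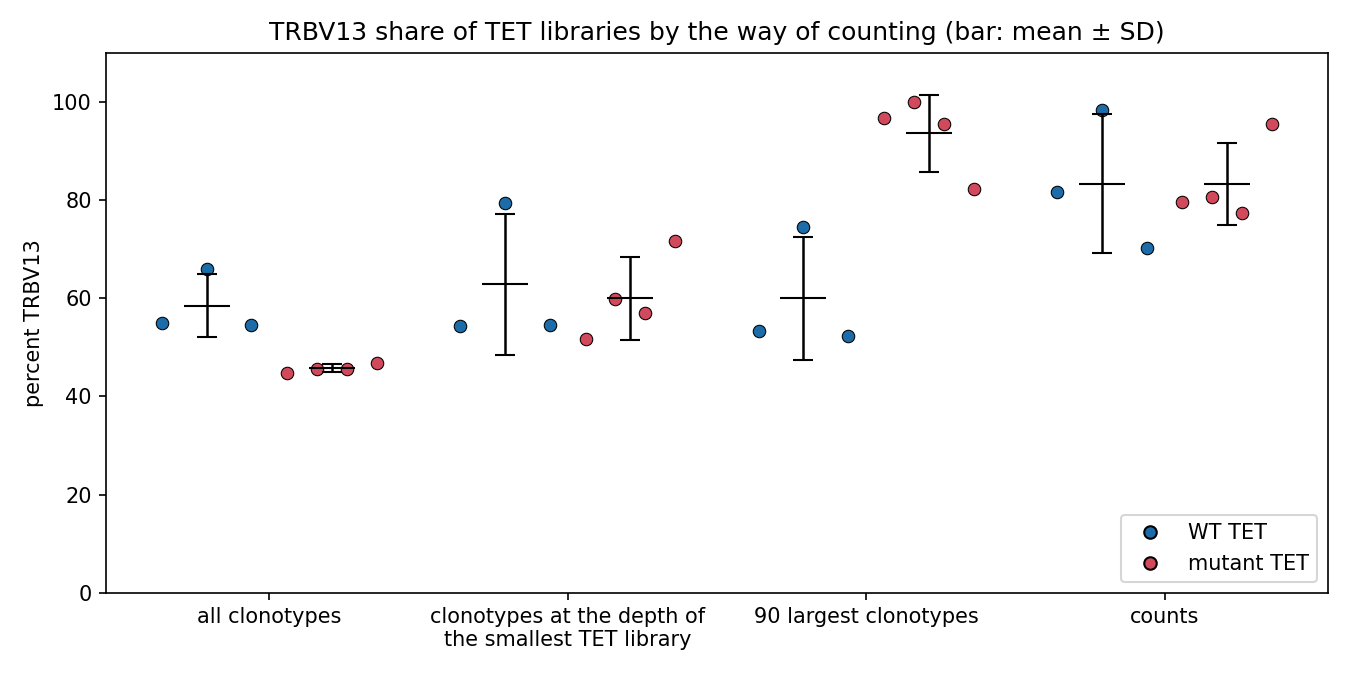
TRBV13 share of the WT and mutant TET libraries over all clonotypes, over clonotypes at the depth of the smallest TET library, over the 90 largest clonotypes of each library and by counts; points are libraries, bars mean ± SD. The strains differ by -12.8 percentage points over all clonotypes and by 33.6 points among the 90 largest, which are most of a WT library and a small part of a mutant one.

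No J segment passed the test between the strains in TET: in edgeR 0 of 12 were called, 3 had an unadjusted p under 0.05, and DESeq2 called 0. TRBJ1-6 made up 4.61 ± 0.545% of mutant and 1.93 ± 1.08% of WT TET clonotypes, with a log2 fold change of 1.37 (SE 0.47, adjusted p = 0.0894), and was called when adjusted over the list alone (1 of 6 TRBJ1 segments, 0 of 6 TRBJ2 segments). TRBJ2-4 made up 8.94 ± 2.15% of mutant and 12.8 ± 2.70% of WT TET clonotypes, with a log2 fold change of -0.66 (adjusted p = 0.133), and was called lower when adjusted over the list alone, a list of 1 member. Without mutant TET 4, 2 segments were called.

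In CD8 libraries, no V family passed the test between the strains. TRBV13 made up 35.8 ± 1.67% of WT and 34.5 ± 0.438% of mutant CD8 clonotypes (n = 4 each), and TRBV26 0.373 ± 0.0726% and 0.405 ± 0.0756%. With edgeR, 0 of 17 V families were called, 0 had an unadjusted p under 0.05, and DESeq2 called 0; no member of the TRBV13, NKT, MAIT or TRBV26 lists was called when adjusted over the list alone. Of the J segments TRBJ1-3 fell by 0.23 on the log2 scale (SE 0.07, adjusted p = 0.0305), from 4.85 ± 0.546% to 4.28 ± 0.330%, 1 of 12 called and the 1 member of the TRBJ1 list when adjusted over the list alone. TRBJ2-4, at 8.93 ± 0.288% and 9.99 ± 0.486%, had a log2 fold change of 0.16 (adjusted p = 0.0505), and was called higher when adjusted over the list alone, a list of 1 member; 0 of 6 TRBJ2 segments passed when adjusted over the list alone. DESeq2 called TRBJ2-4 and not TRBJ1-3 (adjusted p = 0.105), and the number called ranged from 0 to 3 as single libraries were left out.

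Several receptors recurred among the TET libraries. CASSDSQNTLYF (TRBV13, TRBJ2-4) was found in 6 of 7 TET libraries, by 5 nucleotide sequences, with 8.08 ± 9.05% of the TET counts against a mean of 0.0447% in CD8 (0.0269% without WT CD8 1). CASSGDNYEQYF (TRBV13, TRBJ2-7) was found in 6 of 7 (4.41 ± 4.497%) and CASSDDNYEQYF (TRBV13, TRBJ2-7) in 5 of 7 (1.83 ± 1.71%), each against a lower mean share in CD8 (0.140% and 0.0128%, of which WT CD8 1 held most; 0.0161% and 0.00631% without it). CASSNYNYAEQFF (TRBV13, TRBJ2-1) and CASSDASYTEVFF (TRBV13, TRBJ1-1) were found in 4 TET libraries, all mutant, with 1.62 ± 4.04% and 1.58 ± 4.07% of TET counts. Each mean rests on 1 library, and was 0.0932% without mutant TET 2 and 0.0421% without mutant TET 3. Each had 1 nucleotide sequence in TET. The former had 2416 counts in mutant TET 2 and 20 to 85 in the other mutant libraries, the latter 2376 in mutant TET 3 and 10 to 85. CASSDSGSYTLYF (TRBV13, TRBJ2-4) and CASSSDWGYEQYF (TRBV3, TRBJ2-7) were found in all 3 WT TET libraries and in mutant TET 4, with means of 2.55 ± 4.81% and 0.366 ± 0.775%, which were 0.793% and 0.0743% without mutant TET 4. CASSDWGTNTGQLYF (TRBV13, TRBJ2-2) and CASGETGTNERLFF (TRBV13, TRBJ1-4) were found in 4 TET libraries (1.27 ± 1.82% and 0.0514 ± 0.0852%) and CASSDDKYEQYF (TRBV13, TRBJ2-7) in 3 (1.62 ± 3.39%). Without WT TET 3, mutant TET 2 and mutant TET 3, the largest holder of each, these means were 0.666%, 0.0228% and 0.372%. In all, 45 receptors were found in at least 3 TET libraries, 29 of them TRBV13. Presence in a strain's libraries was not tested, and the mutant TET libraries were deeper than the WT ones. Low counts beside a library that holds many could also come from carry-over between libraries, which was not tested for these receptors.

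The largest clonotype of each TET library, by nucleotide sequence, used TRBV13. In WT mice it was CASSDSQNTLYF with 22.02% of the counts (95% interval 20.9 to 23.2%) in TET 1, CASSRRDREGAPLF (TRBJ1-5) with 15.1% (14.5 to 15.7%) in TET 2 and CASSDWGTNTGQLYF with 4.89% (4.08 to 5.80%) in TET 3. In mutant mice it was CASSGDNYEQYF with 7.99% (7.59 to 8.40%) in TET 1, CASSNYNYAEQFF with 10.8% (10.4 to 11.2%) in TET 2, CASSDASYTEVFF with 10.8% (10.4 to 11.2%) in TET 3 and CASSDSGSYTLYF with 13.1% (12.9 to 13.4%) in TET 4. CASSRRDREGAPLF was found in 2 TET libraries, both WT, and in no CD8 library. Mutant TET 4 and WT TET 2 shared 18 nucleotide clonotypes, which held 88.9% of the counts of the former and 25.4% of those of the latter.

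How far the fractions and the mice held the same clonotypes was measured next. Clonotypes also found in the CD8 library of the same mouse held 10.8 ± 12.1% of the TET counts in WT (n = 3) and 21.3 ± 16.6% in mutant mice (n = 4), a difference of 10.5 points that did not pass the test (exact p = 0.371, adjusted 0.518). It ranged from 3.68 points without mutant TET 4 to 17.4 without WT TET 1, and was 0.643 without clonotypes held at 10 times the count in another library. That filter drops the CD8 copies of large TET clonotypes, and so removes overlap of the kind measured here. Over the 7 mice the share was 16.8 ± 14.8% with the own CD8 library and 5.84 ± 3.71% with those of other mice of the strain, higher with the own in 4 of 7 (exact sign-flip p = 0.188). Pairs of TET libraries shared 5.66 ± 2.53% of their amino acid clonotypes in WT (3 pairs) and 3.45 ± 1.69% in mutant mice (6 pairs; exact p = 0.457, adjusted 0.518); the mutant value was higher by 0.278 without WT TET 2. Between strains the mean was 3.17% over 12 pairs, with a highest value of 19.5% for WT TET 2 and mutant TET 4.

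CDR3 loops, the part of the receptor that contacts the peptide, were slightly shorter in TET when averaged over strains. Their mean length over clonotypes was 13.62 ± 0.197 amino acids in WT TET, 13.86 ± 0.0796 in mutant TET, 13.88 ± 0.0164 in WT CD8 and 13.91 ± 0.0224 in mutant CD8. The difference between fractions was -0.153 amino acids (exact p = 0.00694, adjusted 0.0295), with -0.259 in WT and -0.0471 in mutant mice, and TET was shorter than the own CD8 library in 3 of 3 WT and 2 of 4 mutant mice; it did not pass with the mouse as a block (exact p = 0.0625) or with single-count clonotypes left out (exact p = 0.137). It was -0.0995 without both WT TET 2 and mutant TET 4, and -0.628 by counts (exact p = 0.0049). Between strains, mutant TET was longer by 0.243 (exact p = 0.0857, adjusted 0.208), which did not pass, and by counts the difference was -0.108.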

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

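All tests that weigh an explanation in this part were chosen after the results were seen. Of 124 groups of 4 libraries looked at for a library far from the others, 6 had one, and chance gives about 6.2. Mutant TET 4 held 60164 counts (the others 17294 to 22448). In WT CD8 1 the largest clonotype, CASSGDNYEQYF, took 1.00% of the counts (the others 0.359 to 0.445%). The same receptor recurred among TET libraries, but had 0 counts in WT TET 1. For each TET library but mutant TET 4, the 20 largest clonotypes had their highest CD8 share in WT CD8 1 (0.0701% to 1.29% of its counts). The cause was not tested. TRBV12 made up 5.83% of clonotypes in WT CD8 2 (the others 6.44 to 6.57%), TRBV3 made up 1.53% in mutant TET 4 (0.920 to 1.00%), TRBV30 made up 0.147% in WT CD8 1 (0.286 to 0.301%) and TRBJ1-6 made up 3.79% in mutant CD8 2 (3.29 to 3.34%).

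The strain effect on J use differed between TET and CD8 for 4 of 12 segments in edgeR. The effect in TET less that in CD8 was 0.98 on the log2 scale for TRBJ1-3, 0.78 for TRBJ1-4 and 1.31 for TRBJ1-6 (adjusted p = 0.0492 each), and -0.83 for TRBJ2-4 (adjusted p = 0.0256). This contrast takes the 4 groups as independent, although 7 mice gave both fractions. With the mouse as a block 1 segment was called, TRBJ2-4 (log2 -0.82, adjusted p = 0.0375), and TRBJ1-3 (0.89), TRBJ1-4 (0.76) and TRBJ1-6 (1.29) kept similar values without a call (adjusted p = 0.0716 each). The number called was 1 with TMM factors or DESeq2, 0 by counts and 0 without both WT TET 2 and mutant TET 4, and ranged from 0 to 6 as 1 library was left out. For V families 0 of 15 differed (edgeR, 3 with an unadjusted p under 0.05); DESeq2 called 2.

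Other splits of the same libraries were fitted in the same way. For the V families between fractions (13 called, highest other 11) 1 of 64 splits was as large, a share under 0.05 and the smallest possible. No correction was made over the sets of splits, so this makes chance less likely without excluding it. For the J segments between fractions (11 called; 2 of 64) the share is also under 0.05, but 1 other split called 11 as well. For the V family called between strains in TET (1 called; 1 of 35, highest other 0) the share is under 0.05 too, but that call was lost with TMM factors (log2 -0.12, edgeR adjusted p = 0.438) and without WT TET 2 (-0.27, adjusted p = 0.264). Chance cannot be excluded for the J segments in CD8 (1 called; 3 of 35, highest other 3). The counts of 0 of V families in CD8 (35 of 35, highest other 2) and of J segments in TET (35 of 35, highest other 5) are not tested by this, since with 0 called each split is as large. The splits between fractions swapped TET and CD8 within mice.

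The large clonotypes of mutant TET 4 were also found in WT TET 2, the pair with the highest sharing. Of the 20 largest, 17 were found there and at most 5 in any other TET library, too few for receptors that recur in every mouse to account for most of them; the pair was picked for its sharing, so no p is given. The ratio of counts between the libraries ranged 58.0-fold, from 0.380% to 22.04%, over the 12 shared clonotypes that no other TET library held, which argues against carry-over of finished library molecules at 1 rate. The CD8 library of the same number gave those 20 clonotypes 0.542% of its counts and the next library 0.193%, but this share was highest in the own CD8 library for 1 of the 6 other TET libraries, so it does not tell the mouse. WT TET 2 shared 20 of its clonotypes (15.9%) with mutant CD8 4 and 6 with WT CD8 2. Its largest clonotype, with 15.1% of its counts, had 0 counts in mutant TET 4 and 0 in mutant CD8 4. That is 1 clonotype, and it does not bear on mixing from mutant TET 4 into WT TET 2. Mixing of cells or RNA before amplification and a wrong name of either TET library may each remain, and no other biological explanation was tested.

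TRBV12, TRBV15, TRBV16 and TRBV3 together made up 2.79 ± 1.19% of TET and 22.4 ± 1.44% of CD8 clonotypes. The 4 families were picked as rare in TET from these same data, so the values below are not independent evidence of their rarity. Few clonotypes in the TET libraries cannot account for it, since 109 were found where the CD8 shares of the same mice give 1238. Non-tetramer cells as the main source of the TET clonotypes with a count of 5 or less are argued against as well. Among these, the 4 families made up 4.41% in TET (at most 8.93% in a library) and 25.02% in CD8 (at least 23.3%, exact p = 0.000408, the smallest possible). That p largely restates the rarity for which the families were picked. What stays open is a smaller part from such cells, and cells that neither fraction samples. Binding of the IGRP tetramer, the difference the design names, may underlie the pattern, as an untested hypothesis.

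The lower TRBV13 share of mutant TET clonotypes was set against depth and clone size. At the depth of the smallest TET library the difference was -2.79 percentage points (exact p = 0.714), as the larger depth of the mutant libraries would give. This does not decide for depth, since subsampling keeps large clonotypes, and TRBV13 clonotypes were larger than others. WT TET 2 and mutant TET 1, of similar depth (14958 and 17294 counts), held 65.9% and 44.8% TRBV13 clonotypes. This 1 pair does not decide against depth. The libraries held 126 and 997 clonotypes, so equal counts need not mean equal sampling of cells. WT TET 2 also had the highest WT share (the others 54.9% and 54.6%) and is in doubt for its sharing with mutant TET 4. Among clonotypes of at least 0.1% of the counts, the same limit in each library, TRBV13 was 27.4 points higher in mutant mice. That limit kept 58 to 84 of the 97 to 126 clonotypes of WT libraries and 34 to 217 of the 393 to 2199 of mutant ones. Tested against -12.8 points, the difference over all clonotypes, the 27.4 points gave exact p = 0.0286, the smallest possible. The -12.8 was taken as a fixed value although it was estimated from the same libraries, so this p leaves out its error. Unlike parts of the size range are compared, so this does not decide whether mutant mice have fewer TRBV13 receptors among large clonotypes. At 1% or more the difference was 1.61, and the same test against -12.8 did not pass (exact p = 0.143). A strain difference, which the design names, stays open as untested.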

How the results depend on the processing

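Of 389 alternative values of the main results, 336 kept their direction and side of the threshold or moved little, 26 moved, 14 lost the call and 13 reversed. An exact test that missed the threshold counts as kept while it misses it with the same sign, whatever its size. Strain tests in TET with 1 library left out cannot pass it at all. The tally therefore does not measure how stable the sizes were. Among the others, 41 of 658 values of called segments lost the call and 18 reversed, and 0 of 110 for clonotype shares moved by more than their SD between libraries, which is wide. Of 88 values for the 4 J segments whose strain effect differed between fractions, 57 lost the call. The effective number and the share of the 10 largest clonotypes, TET against CD8, kept direction and call under each alternative run. Where a cause is not given, the cause was not tested. The TRBV13 share of TET clonotypes, mutant less WT, was -7.11 percentage points without single-count clonotypes (exact p = 0.457), -0.0840 by counts and -9.45 without both WT TET 2 and mutant TET 4, and ranged from -14.7 to -9.07 as 1 library was left out, with fewer libraries and so a smallest exact p of 0.0667 or 0.1. Chosen after the data were seen, it was -2.79 at equal depth, 27.4 among clonotypes of at least 0.1% of the counts and 33.6 among the 90 largest. Mean CDR3 length, mutant less WT in TET, was -0.108 by counts, -0.154 among clonotypes of at least 0.1% and -0.155 among the 90 largest; TET less CD8 was -0.151 without single-count clonotypes (exact p = 0.137). The share of TET clonotypes, in place of counts, also in the own CD8 library differed by -0.475 points. Leaving out 1 library, the difference in the share of the 10 largest ranged from -12.5 to 8.80 in TET and from -0.436 (without mutant CD8 4) to 0.831 in CD8, where it was -0.213 without WT CD8 4, and that in sharing between TET libraries from -4.78 to 0.278. Sharing differed by 0.353 points without clonotypes held at 10 times the count elsewhere and 1.59 without both libraries in doubt.

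The V family count of 1 in TET between strains was 0 with TMM factors, no filter, weighting by counts, single-count clonotypes left out (5 families tested), clonotypes held elsewhere left out and both libraries in doubt left out, and ranged from 0 to 2 as 1 library was left out. J segments called there ranged from 0 to 2. J segments called in CD8 (1) were 0 with TMM factors and by counts, 2 with near-identical clonotypes merged or those held elsewhere left out, and ranged from 0 to 3 as 1 library was left out. The median log2 fold change of V families was 0.66 between strains in TET (0.91 with TMM factors, 0.16 with DESeq2) and 0.00 between fractions (-0.21 and -0.31), and that of J segments between fractions was 0.18 (-0.01 and 0.06). Between fractions in WT alone, with fewer libraries, 6 V families and 1 J segment were called, and 0 J segments by counts. By counts the log2 fold changes were -0.52 for TRBV1, -0.44 for TRBV2, -0.14 for TRBV31, -0.66 for TRBV5, -0.13 for TRBJ1-1, -0.021 for TRBJ1-2, -0.41 for TRBJ1-3, -0.12 for TRBJ1-4, -1.38 for TRBJ1-6, 0.12 for TRBJ2-2, 1.13 for TRBJ2-4 and 0.34 for TRBJ2-7. In WT alone they were -0.12 for TRBV5, -0.32 for TRBJ1-3, -0.0074 for TRBJ1-4, -0.82 for TRBJ1-6, 0.056 for TRBJ2-2 and 0.53 for TRBJ2-4.

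With the replicate number as a block, 17 of 21 main results kept their call. With the mouse as a block, the CDR3 difference between fractions was -0.151 (exact p = 0.0625), TRBJ2-4 was no longer called, and the block changed no other call of a main result between fractions. Between strains the mice share only a number: the correlations of V use over 15 families between same-numbered libraries were 0.329, -0.137 and -0.0841 in TET and -0.583, 0.514, -0.211 and 0.0360 in CD8. Under that block the TRBV13 difference was -13.1 points (exact p = 0.250, the smallest that 3 pairs allow), and the V families called in TET and the J segments called in CD8 were 0 each. Keeping out-of-frame sequences was not run, since the tables hold none, and clonotypes of at least 0.1% left too few segments for a count of calls. In TET, mutant against WT, a 2-fold lower V family was recovered in 50% of simulations.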

Other observations

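The measures in this part were chosen after the data were seen, 9 tests in all, with Benjamini-Hochberg adjusted p over them. Repeats without WT TET 2 and mutant TET 4 are not adjusted. The exact tests reassigned the fraction among the libraries of a strain and did not use the pairing by mouse. No test with the mouse as a block was run for these measures, so the numbers of mice are descriptive. TRBV13 receptors with a 12-amino-acid CDR3 and TRBJ2-7, the form of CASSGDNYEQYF and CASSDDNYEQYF, took 20.001 ± 10.8% of TET counts (n = 7) and 2.43 ± 0.661% of CD8 counts (n = 8), higher in 7 of 7 mice (exact p = 0.000408, the smallest possible, adjusted 0.00245). By clonotypes the shares were 3.99 ± 2.88% and 1.69 ± 0.356% (exact p = 0.00612, adjusted 0.0122), higher in 5 of 7 mice. Those with TRBJ2-4, the form of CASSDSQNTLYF, took 13.8 ± 14.2% of TET and 0.643 ± 0.205% of CD8 counts, higher in 6 of 7 mice (exact p = 0.00816, adjusted 0.0122), and 7.62 ± 9.61% of TET counts without WT TET 2 and mutant TET 4 (n = 5). By clonotypes they made up 2.04 ± 2.52% and 0.400 ± 0.109%, higher in 5 of 7 mice (exact p = 0.0384, adjusted 0.0493); without those 2 libraries the TET value was 0.921 ± 1.18% and the difference did not pass the test (exact p = 0.190). These forms were defined from receptors that recur in these same libraries, so the tests are not independent evidence.

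TRBV13 clonotypes were also larger than others within TET libraries. The mean count of a TRBV13 clonotype was 10.6 ± 11.6 times that of other clonotypes in TET (n = 7) and 1.78 ± 0.165 times in CD8 (n = 8), a difference of 1.87 in log2 averaged over strains, higher in 7 of 7 mice (exact p = 0.000816, adjusted 0.00245). The mean was carried by WT TET 2 (30.1 times) and mutant TET 4 (24.6 times), and without them it was 3.89 ± 1.21 times (n = 5), with a log2 difference of 0.99 (exact p = 0.00381). The TRBJ1 cluster made up 37.9 ± 7.42% of TET and 28.2 ± 1.70% of CD8 clonotypes, higher in 6 of 7 mice (exact p = 0.00816, adjusted 0.0122). By counts its shares were 26.2 ± 14.1% and 28.1 ± 1.73%, which did not differ past the test (exact p = 0.744). TRBD2 was named in 39.2 ± 6.26% of TET and 43.7 ± 0.502% of CD8 clonotypes with a TRBJ2 segment (exact p = 0.105, adjusted 0.118). Summed over the pairs of TET libraries, sharing of an amino acid receptor was counted 517 times, once per pair that held it, 40 of them by different nucleotide sequences alone.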
